A study of Mus musculus with 9 samples.

How the data were processed

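RNA from mouse spinal cord was sequenced in 9 libraries, 3 each from the groups named sham, SNI and SNI+LDN193189 in the labels. Per the labels, RNA was selected by its poly(A) tail, made into strand-marked libraries and read as 150 bp pairs, in a protocol text that speaks of cell lines. The deposited counts table holds whole-number read counts for 40879 gene symbols, with 1 column per library. The deposited FPKM table holds values for the same symbols that the authors derived from those counts, scaled by gene length and library total. In each library the FPKM equalled the count divided by the library total and by 1 fixed length per gene, for 26285 of the genes with a count, within a relative tolerance of 1e-09. The submitters' processing notes name the mouse build mm10, and the aligner, the counting tool and the annotation release were not given in the sources used here. The segment and side of the cord, the time after injury and the dose, route and vehicle of the compound were not in the labels either.

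The columns carry the letters L, S and N with a replicate number. L was read as LDN193189, S as sham and N as SNI, from the names alone and before any value was looked at. If S stood for SNI and N for a word outside the labels, each direction between sham and SNI would turn and the comparisons of SNI+LDN193189 with SNI and with sham would change places. A later look at Sprr1a, a gene of injured neurons, found 0.161 to 0.235 CPM (counts scaled to a common library total) in the columns read as sham and 6.62 or more in those read as SNI. That look was a check and not the basis of the reading.

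Totals ran from 33432776 to 37190467 counts, a ratio of 1.11 between the highest and the lowest. Between 21758 and 22457 genes had a count in a library, and the 10 most abundant genes took 8.69 to 9.87% of the counts. Of the counts above 0 between 70.7 and 71.8% of a library were even, for which the labels give no reason. In 14594 genes the count was 0 in all libraries. Among protein-coding genes this held for 616 of 629 genes lying wholly inside another gene and for 1048 of 10613 genes without an overlap, so such genes are described as listed at 0, not as silent. They include 46 of the 715 distinct genes of the lists described next, Casp1, Il1b, Casp4, Csf1, Aqp4 and P2ry12 among them.

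The main test was the edgeR (4.0.16) quasi-likelihood F test with robust fitting in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 18245, and libraries were scaled by TMM factors of 0.984 to 1.02. All 9 libraries entered 1 fit of group means with 6 residual degrees of freedom, a biological coefficient of variation of 0.132 and a median standard error of the log2 fold change of 0.118. P-values were adjusted by Benjamini-Hochberg (BH) over all genes tested and called under 0.05. The 3 comparisons between groups and a joint test of the 3 groups were made. Symbols were placed on the genome with GENCODE M21 on GRCm38. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for tables and figures.

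Before the data were examined, 49 gene lists for pathways, cell types of cord and neighbouring tissue, and sample checks were fixed, together with the tests, most alternatives and the rule for the genes named. Lists with at least 3 tested members, 48 of them, were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, and adjusted by BH over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves on balance in a direction without reference to other genes, were run beside it. The rule named the genes past the threshold with the largest changes or, where fewer than 5 qualified, the 10 named genes with the smallest p. It added up to 4 members with the smallest p of each list described and 20 genes fixed by name for the study's subject. Genes whose levels per library are given outside this rule were chosen after their values were seen, and are said to be so.

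To ask whether genes moved by injury moved back with the compound, the log2 fold changes of SNI against sham and of SNI+LDN193189 against SNI were correlated over genes. Both contain the SNI libraries with opposite sign, so 100 simulated tables with SNI means in both injured groups and 100 with no group effect gave the value expected from that alone. The fit was tested on simulated data with 3 libraries per group: of genes given a log2 change of 1, it recovered 73.1% in SNI against sham, 71.6% in SNI+LDN193189 against SNI and 68.7% in SNI+LDN193189 against sham. Between 6.43 and 11.7% of the simulated calls were false. The simulated tables held many planted changes and no library with added nerve root or muscle, so these shares may not hold in the data.

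Alternatives to these choices comprised DESeq2 1.42.0, limma-voom with sample weights, limma on log2 FPKM, other scalings and filters, a replicate block, a threshold on the fold change and leaving out each library in turn. Genes that DESeq2's independent filtering left without an adjusted p were not counted there. Fits with the nerve root level or a clock score as a covariate, a fit with counts halved and rounded up, and a fit without sham replicate 1 and SNI+LDN193189 replicate 3, were added after seeing the data. The root level is the mean centred log2 CPM of the Schwann cell and nerve root list in a library. The clock score is the centred mean log2 CPM of Dbp, Tef, Per3, Nr1d1 and Nr1d2 minus that of Bmal1 and Npas2, and holds neither Per1 nor Per2, while the choice of its genes followed a look at the data. The replicate numbers were not treated as pairs, since only 2 of 9 same-number pairs of libraries correlated above 0.1 once group means were removed. Pairing is not excluded, as 5 of 9 libraries correlated best with a library of their own number. The highest correlation was 0.144 among same-number pairs and 0.132 among the other pairs. Nothing in the labels gives a batch or a date, and 0 per-sample columns were left unused.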

Results

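Spinal cord from male mice was profiled by RNA sequencing in 9 libraries, 3 from the sham group, 3 from SNI and 3 from SNI+LDN193189. In pain research SNI stands for spared nerve injury, in which part of the sciatic nerve is cut and the rest is left intact. LDN193189 is a small-molecule inhibitor of BMP receptor kinases, ACVR1 among them. The series title names ACVR1, glycolysis, histone lactylation and pyroptosis of neurons, so lists for these subjects stood beside lists for pain, inflammation and cell types. The lists hold RNA levels of whole cord. They do not measure kinase activity, lactylation of histones or pyroptosis of neurons themselves. Each library held 33432776 to 37190467 counts, and 18245 genes were tested. The labels call the replicates separate biosamples and say nothing of separate animals, so the p-values measure only the spread between these samples. Levels are given in CPM, counts scaled to a common library total, as mean ± SD with n = 3 per group. Adjusted p-values of genes come from edgeR quasi-likelihood tests with BH.

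SNI against sham asked what the nerve injury did to the cord. Genes of the axotomy response, which neurons switch on when their axons are cut, rose in SNI, with 16 of 20 measured members higher. Sprr1a, a gene of regenerating neurons, stood at 14.9 ± 8.18 CPM in SNI and 0.204 ± 0.0382 in sham, a log2 fold change of 6.17 (SE 1.41). Atf3, a transcription factor of injured neurons, stood at 8.89 ± 3.21 in SNI and 1.86 ± 1.05 in sham, and Gal, which encodes the neuropeptide galanin, at 6.17 ± 1.68 and 3.34 ± 0.412. Microglial markers rose as well, 11 of 14 being higher. Cx3cr1, the fractalkine receptor, stood at 46.1 ± 3.95 in SNI and 37.3 ± 3.66 in sham, and Csf1r, the receptor that microglia need to survive, at 75.3 ± 1.60 and 66.0 ± 2.93. Camera gave the axotomy list an adjusted p = 1.89e-05 with a median log2 fold change of 0.10 and a mean of 0.53, and an adjusted p = 0.501 with an estimated correlation. Gal and Sprr1a were the 2 axotomy genes that passed adjusted over the list alone, and over all genes 0 passed with edgeR and Sprr1a with DESeq2. The microglia list had an adjusted p = 0.000135 and a median of 0.15, and an adjusted p = 0.501 with an estimated correlation. Cx3cr1 and Csf1r were the 2 members that passed adjusted over the list alone, and over all genes 0 passed with edgeR or DESeq2. Sprr1a lies on chromosome 3 at 92483952 to 92485895 and Atf3 on chromosome 1 at 191170296 to 191218039 in GRCm38.

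**Figure D1:**
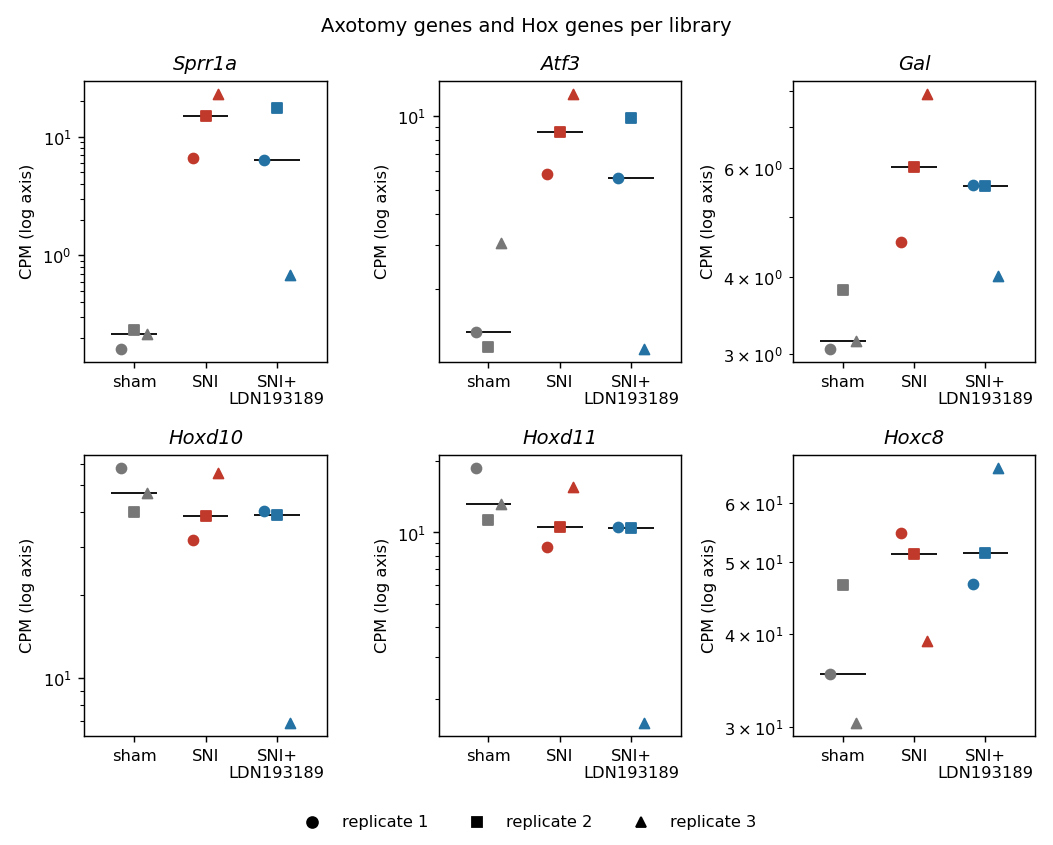
CPM on a log axis for axotomy response genes and Hox genes, with a point per library, a line at the group median and a symbol per replicate. Hoxd10 and Hoxd11 are posterior Hox genes, while Hoxc8 is from the list of cervicothoracic Hox genes. Sprr1a stayed at 0.161 to 0.235 CPM in sham and stood at 6.62 or more in SNI, while SNI+LDN193189 replicate 3 held 0.688 CPM of Sprr1a and 6.85 CPM of Hoxd10.

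Markers of peripheral nerve root, membranes, muscle and ganglion were lower in SNI against sham. All 10 Schwann cell and nerve root markers were lower. Pmp2, a peripheral myelin gene, stood at 3.70 ± 2.44 CPM in SNI and 27.8 ± 26.7 in sham, and Dhh, a signal that Schwann cells secrete, at 3.00 ± 1.70 and 18.8 ± 17.3. In sham replicates 1, 2 and 3 Pmp2 stood at 5.90, 20.1 and 57.5 CPM and in those of SNI at 0.912, 4.74 and 5.45. Of the skeletal muscle markers 11 of 12 were lower. Acta1, skeletal actin, reached 222 CPM in sham replicate 1 and at most 4.16 in any other library. Without sham replicate 3 the log2 fold change went from -2.90 to -1.80 for Pmp2 and from -2.64 to -1.58 for Dhh, and without sham replicate 1 from -6.78 to -2.16 for Acta1. The camera adjusted p was 1.86e-13 for the nerve root list, whose median log2 fold change was -2.21, and 6.57e-08 for the muscle list, and each had an adjusted p = 0.501 with an estimated correlation. In each list 9 members fell when adjusted over the list alone, and over all genes 0 did with edgeR or DESeq2. Markers of dorsal root ganglion neurons fell with a median of -1.42 (camera adjusted p = 0.00161, adjusted p = 0.535 with an estimated correlation), and without sham replicate 2, whose Scn10a stood at 11.8 CPM, the adjusted p was 0.591. With covariates added after seeing the data the ganglion list had an adjusted p of 0.240 (nerve root level) and 0.552 (clock score).

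**Figure D2:**
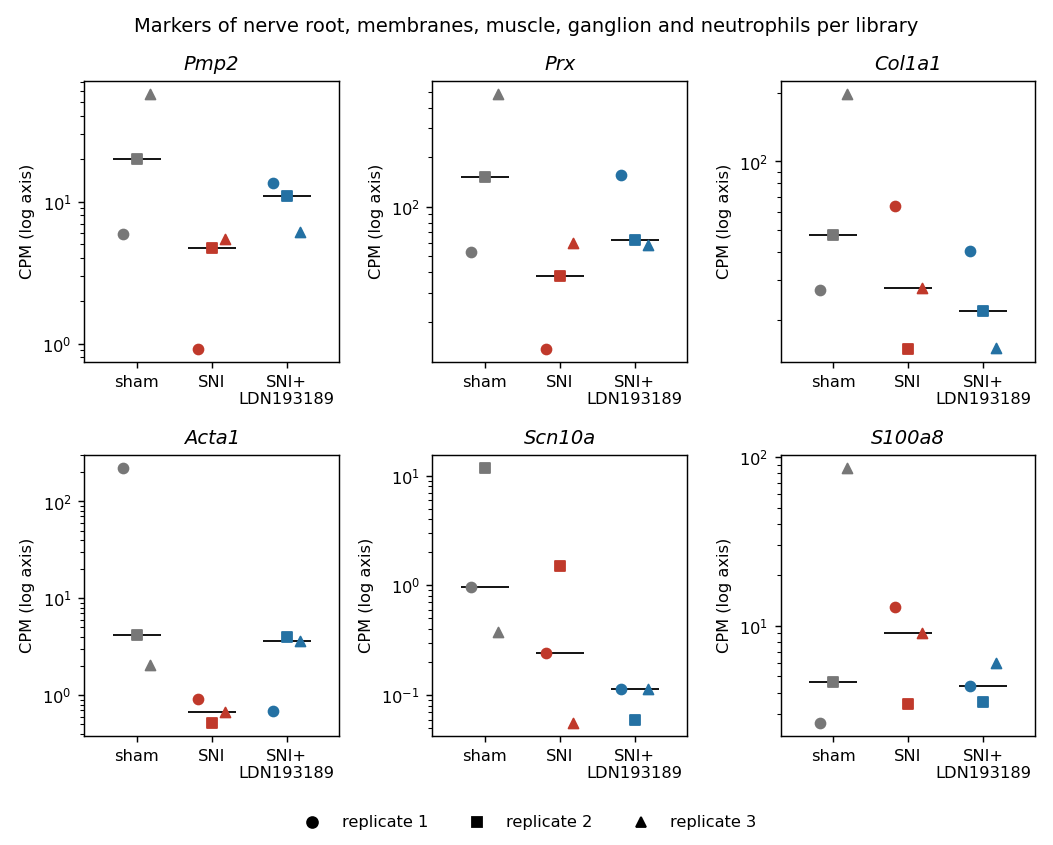
CPM on a log axis for markers of nerve root, membranes, muscle, ganglion and neutrophils, with a point per library, a line at the group median and a symbol per replicate. Single sham libraries held the highest levels, such as 57.5 CPM of Pmp2 in sham replicate 3 and 222 CPM of Acta1 in sham replicate 1.

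Connective tissue genes moved with those markers in SNI against sham. Extracellular matrix genes fell, 16 of 17 being lower. Col6a2, a chain of type VI collagen, stood at 5.94 ± 0.336 CPM in SNI and 11.8 ± 4.51 in sham and Mmp2, a gelatinase, at 5.72 ± 0.662 and 8.07 ± 1.90. Markers of meningeal fibroblasts fell too, all 12 being lower. The small proteoglycan gene Lum stood at 4.11 ± 1.01 and 12.1 ± 6.61 and Dcn at 33.1 ± 14.4 and 118 ± 82.0. Perivascular macrophage markers fell, with Cd163, a hemoglobin scavenger receptor, at 1.44 ± 0.474 and 2.45 ± 0.748. Sham replicate 3, which had the most Pmp2, also held 199 CPM of Col1a1, a fibroblast collagen chosen after its values were seen, while the other libraries held 14.9 to 63.3. Camera gave adjusted p-values of 2.29e-11 for the matrix list (median -0.32), 5.11e-08 for fibroblasts (median -1.22) and 0.000135 for macrophages (median -0.77), and each had an adjusted p = 0.501 with an estimated correlation. Adjusted over the list alone 4 matrix genes fell, Col6a2, Col6a1, Mmp14 and Mmp2, and over all genes 0 did with edgeR and Col6a2 with DESeq2. Without sham replicate 3 the log2 fold change went from -0.993 to -0.650 for Col6a2, from -0.468 to -0.310 for Col6a1, from -0.496 to -0.296 for Mmp2 and from -1.83 to -1.16 for Dcn. Erythrocyte markers fell with a median of -0.69 (camera adjusted p = 0.00136, adjusted p = 0.501 with an estimated correlation). Ependymal markers fell with a median of -0.25 (camera adjusted p = 0.0129, adjusted p = 0.535 with an estimated correlation). Leaving out sham replicate 3 gave an adjusted p of 0.176 for macrophages and 0.282 for ependyma, leaving out SNI replicate 1 gave 0.342 for ependyma, and leaving out SNI replicate 2 gave 0.0702 for erythrocytes. These 5 lists lost their calls with the nerve root level as a covariate, with adjusted p-values of 0.763 for matrix, 0.264 for fibroblasts and erythrocytes, 0.894 for macrophages and 0.773 for ependyma.

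Markers of cord cells and of energy metabolism were slightly higher in SNI against sham, beside the lower markers of other tissue. Of the neuronal markers 13 of 14 were higher (median 0.10) and of the oligodendrocyte and myelin genes 13 of 15 (median 0.09). Of the tricarboxylic acid cycle genes 19 of 20 were higher (median 0.06), of nuclear oxidative phosphorylation genes 26 of 30 (median 0.06) and of glycolysis and lactate genes 20 of 26 (median 0.05). Opalin, a gene of myelinating oligodendrocytes, stood at 87.6 ± 5.83 CPM in SNI and 66.8 ± 2.50 in sham and was the 1 myelin gene that passed adjusted over the list alone, and with DESeq2 over all genes. Eno1, the glycolytic enolase, stood at 464 ± 7.85 and 434 ± 9.05, and 0 of the 26 glycolysis genes passed adjusted over the list alone or, with edgeR or DESeq2, over all genes. The camera adjusted p-values were 6.35e-05 for neurons, 0.000141 for myelin, 0.000558 for both mitochondrial lists and 0.00767 for glycolysis. In the same order the lists had an adjusted p = 0.535, 0.501, 0.589, 0.599 and 0.501 with an estimated correlation. Without sham replicate 3 the adjusted p was 0.158 for neurons, 0.127 for the tricarboxylic acid cycle, 0.0664 for oxidative phosphorylation and 0.0925 for glycolysis, and without SNI replicate 1 it was 0.0898 for glycolysis. With the nerve root level as a covariate, a fit added after seeing the data, all 5 lists lost their call. The adjusted p was then 0.521 for glycolysis (median 0.018), 0.645 for neurons (median 0.019), 0.393 for the tricarboxylic acid cycle (median 0.026), 0.167 for oxidative phosphorylation (median 0.024) and 0.0628 for myelin (median 0.056).

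Interferon response genes rose in SNI against sham, 14 of 16 being higher. Ifi44 stood at 5.93 ± 5.56 CPM in SNI and 2.61 ± 0.293 in sham and the antiviral gene Rsad2 at 7.35 ± 4.86 and 4.13 ± 0.794. The list was carried by SNI replicate 3, since without that library its direction turned, with an adjusted p of 0.0345. Reactive astrocyte genes fell, 10 of 15 being lower, with the oncostatin M receptor gene Osmr at 8.68 ± 0.811 and 13.2 ± 1.48. Sphk1, a sphingosine kinase, rose instead when adjusted over the list alone, to 4.71 ± 0.521 from 3.17 ± 0.165. Heat shock and unfolded protein genes and glucocorticoid response genes fell with medians of -0.10 and -0.09. Camera gave adjusted p-values of 0.0022 for interferon, 0.00348 for astrocytes, 0.012 for heat shock and 0.0147 for glucocorticoid genes. These lists had an adjusted p = 0.816, 0.535, 0.809 and 0.816 with an estimated correlation. Adjusted over the list alone 3 astrocyte genes passed, Osmr, S1pr3 and Sphk1, and over all genes 0 of any of these lists did with edgeR, and Osmr and S1pr3 with DESeq2. Leaving out sham replicate 1 gave adjusted p-values of 0.0949 for interferon and 0.249 for heat shock. Leaving out sham replicate 2 gave 0.0735 for interferon, 0.0760 for astrocytes, 0.136 for heat shock and 0.885 for glucocorticoid genes. Sham replicate 3 left out gave 0.0925 for astrocytes. Leaving out SNI replicate 2 gave 0.305 for glucocorticoid genes and leaving out SNI replicate 3 gave 0.816 for heat shock. The log2 fold changes of Ifi44 and Rsad2 went from 1.18 and 0.832 to 0.0619 and 0.139 without SNI replicate 3, and that of S1pr3 from -0.961 to -0.608 without sham replicate 3. With the nerve root level as a covariate the astrocyte median turned to 0.128 (adjusted p = 0.247). With the clock score the interferon list was called lower (median -0.370, adjusted p = 0.00028) and the heat shock median turned to 0.058 (adjusted p = 0.0732). The glucocorticoid list lost its call with either covariate, with an adjusted p of 0.225 for the root level and 0.0644 for the clock score.

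Of the 48 lists tested in SNI against sham, camera called 19, 8 higher and 11 lower. With an estimated correlation 0 were called (lowest adjusted p 0.501), and fry called 0 (lowest adjusted p 0.514). In SNI+LDN193189 against SNI camera called 13, 9 higher and 4 lower, a count that was 21 without SNI replicate 3 and 8 without SNI+LDN193189 replicate 1 and without SNI+LDN193189 replicate 3. In SNI+LDN193189 against sham it called 20, 8 higher and 12 lower. With an estimated correlation 0 lists were called in these comparisons (lowest adjusted p 0.315 and 0.278), and fry called 0 (lowest adjusted p 0.812 and 0.349).

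**Figure D3:**
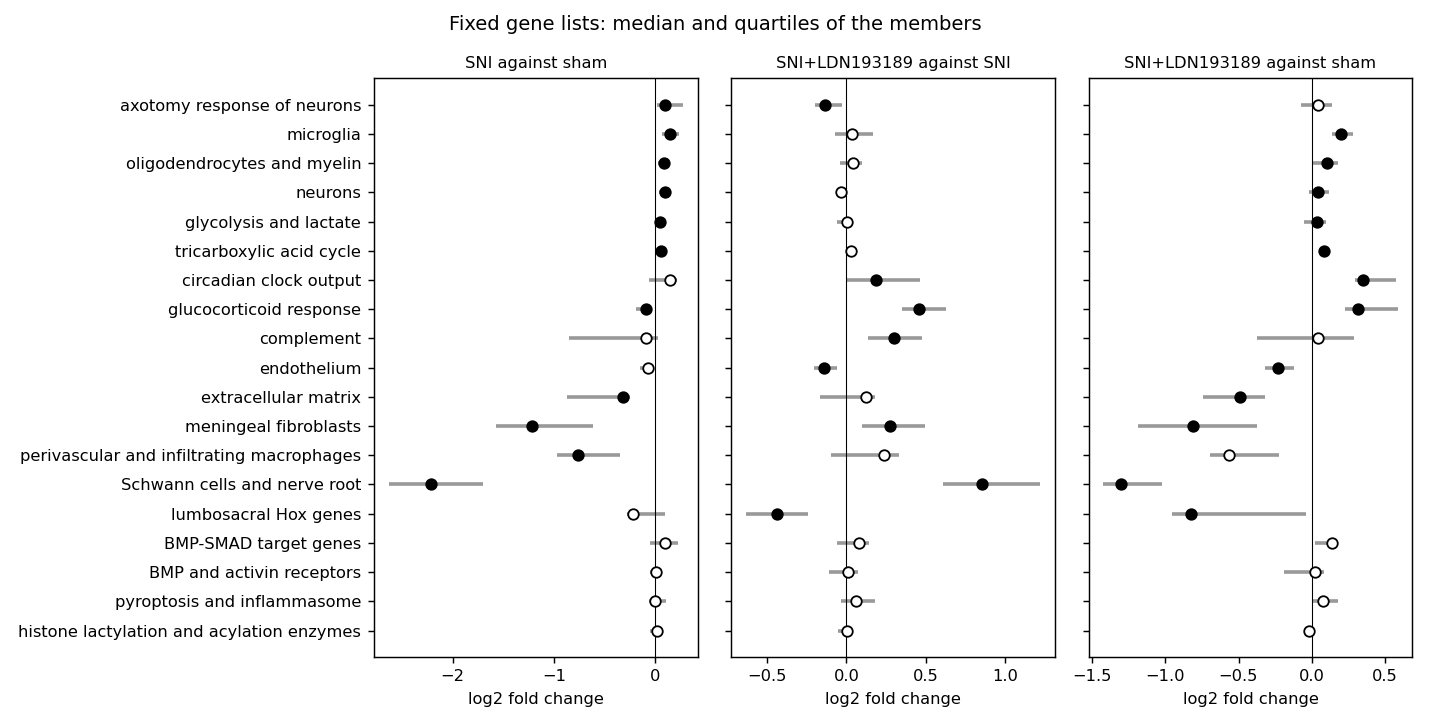
Median log2 fold change of 19 gene lists in each of the 3 comparisons, with grey bars for the quartiles of the members and filled points for lists called by camera with its preset correlation. In SNI against sham the nerve root list stood at -2.21 and the axotomy list at 0.10, and in SNI+LDN193189 against SNI the glucocorticoid list stood at 0.46.

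The lists nearest to the study's title were not called in SNI against sham apart from glycolysis. BMP-SMAD target genes had a median of 0.10 (camera adjusted p = 0.273). Pyroptosis and inflammasome genes had a median of -0.00 and a mean of 0.01 with the test pointing up (adjusted p = 0.841), and histone lactylation enzymes a median of 0.01 (adjusted p = 0.841). The BMP and activin receptors had a median of 0.01, a mean of -0.04 and a test pointing down (adjusted p = 0.879). Cytokines and chemokines had a median of 0.27 and a mean of 0.36 while the test pointed down (adjusted p = 0.841), with 1 member lower when adjusted over the list alone. Reactive microglia genes had a median of 0.01, a mean of -0.08 and an adjusted p of 0.941, but were called higher with the nerve root level as a covariate (median 0.298, adjusted p = 0.00425). Casp1 and Il1b, the inflammasome protease and the cytokine it releases, were listed at 0 in all libraries, as were 4 of the 19 pyroptosis genes in the table.

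No single gene passed with edgeR in SNI against sham. The edgeR count was 0 while 972 genes had an unadjusted p under 0.05 (368 higher and 604 lower, 912.25 being expected by chance) and the lowest adjusted p was 0.62. DESeq2 called 25 genes, 4 higher and 21 lower, Sprr1a, Aqp1 and Col6a2 among them, limma-voom called 0, and edgeR without sham replicate 1 called 38, all lower. The genes with the smallest p did not pass with edgeR, with adjusted p-values of 0.62 to 0.639, though Aqp1, H19 and Mpdz were among those that DESeq2 called. The water channel Aqp1 stood lower, at 1.09 ± 0.443 CPM in SNI and 3.82 ± 1.35 in sham, and so did the imprinted RNA H19 at 0.953 ± 0.340 and 4.09 ± 2.59, and Sat1, an enzyme of polyamine breakdown, at 66.2 ± 2.79 and 81.9 ± 6.18. Mpdz, a scaffold protein gene, stood at 82.6 ± 3.42 and 104 ± 10.6 and Cyp2j13 at 0.0925 ± 0.0598 and 1.01 ± 0.876. Higher values were seen in the phosphodiesterase Pde8a at 79.5 ± 3.03 and 66.1 ± 2.05 and in Sytl2, a gene of vesicle transport, at 100.2 ± 3.27 and 82.1 ± 5.29. Without sham replicate 1, Osmr, Mpdz and Cyp2j13 passed with adjusted p-values of 0.0415, 0.0335 and 0.0429.

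SNI+LDN193189 against SNI asked what the receptor inhibitor changed in injured mice. Mmp14, a membrane-bound protease that cleaves collagen and other matrix, fell to 18.8 ± 2.13 CPM from 32.0 ± 2.95, a log2 fold change of -0.77 (SE 0.0988). Glucocorticoid response genes rose, all 15 being higher. The feedback gene Fkbp5 stood at 40.6 ± 8.89 CPM and 29.5 ± 0.408, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 202 ± 20.7 and 158 ± 10.3, and Per1, a clock gene that glucocorticoids also induce, at 48.0 ± 4.74 and 30.9 ± 5.94. SNI+LDN193189 replicate 3 held the most of all 3, and without it the log2 fold change of Fkbp5 went from 0.459 to 0.274 and that of Errfi1, of the same list, from 0.348 to 0.184. Circadian clock genes moved with them. The clock repressor genes Per2 and Cry1 stood at 28.9 ± 2.68 and 18.3 ± 2.86, and at 24.4 ± 0.860 and 17.7 ± 2.88. The clock activator genes stood lower, Bmal1 at 15.3 ± 0.673 and 20.5 ± 3.78 and Npas2 at 8.15 ± 0.534 and 11.3 ± 2.04. Camera gave the glucocorticoid list an adjusted p = 1.89e-22 (median 0.46) and the clock list an adjusted p = 2.06e-05 (median 0.19, 10 of 13 higher), and each had an adjusted p = 0.315 with an estimated correlation. Adjusted over the list alone 4 glucocorticoid genes rose, Tsc22d3, Fkbp5, Per1 and Errfi1, and 7 clock genes changed, 5 up and 2 down, while over all genes 0 of either list passed with edgeR, and Per1, Per2 and Tsc22d3 with DESeq2. Dbp, a clock output gene chosen after its values were seen, stood at 40.5, 47.5 and 36.3 CPM in SNI+LDN193189 replicates 1, 2 and 3 and at 20.7, 23.3 and 41.5 in those of SNI. The glucocorticoid list contains Per1, which the clock list holds too.

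**Figure D4:**
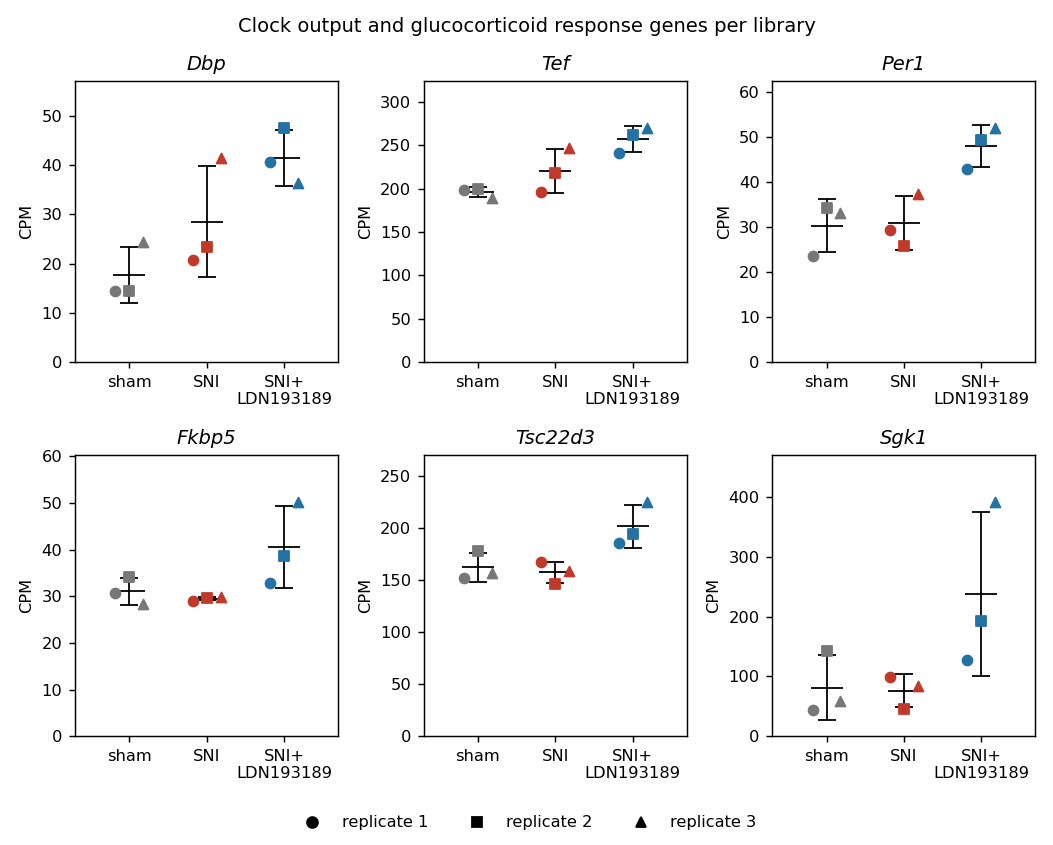
CPM of clock output and glucocorticoid response genes on a linear axis from 0, with a point per library and the mean ± SD of each group. Dbp in SNI replicate 3 stood at 41.5 CPM, inside the SNI+LDN193189 range of 36.3 to 47.5, while Tsc22d3 stayed at 147 to 167 CPM in SNI and 186 to 225 in SNI+LDN193189.

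Mmp14, on chromosome 14 at 54431612 to 54445364 in GRCm38, was the 1 gene that passed in SNI+LDN193189 against SNI with edgeR, at an adjusted p of 0.0194. With an unadjusted p under 0.05 there were 708 genes, fewer than the 912.25 expected by chance. DESeq2 called 7 genes, Mmp14, Per2, Elk1, Vstm4, Per1, Tsc22d3 and Kdr, and limma-voom called 1. Mmp14 did not overlap between the groups, its lowest level in SNI being 28.6 CPM, which chance gives in 10% of genes with 3 libraries against 3. Its adjusted p over the alternatives ran from 3.16e-08 to 0.28. It was 0.28 without SNI replicate 1, 0.271 without SNI replicate 2, 0.121 without SNI+LDN193189 replicate 2, 0.28 without SNI+LDN193189 replicate 3 and 0.231 to 0.248 on FPKM. With the replicate numbers as a block the edgeR adjusted p of Mmp14 was 0.073. The count of genes was 2 without sham replicate 2 and 2 without SNI replicate 3, where Per2 passed at 0.0202. Per2 had an adjusted p of 0.226 with all libraries. The other genes with the smallest p had an adjusted p of 1.0. Tmod1, which caps actin filaments, stood at 16.5 ± 2.44 CPM in SNI+LDN193189 and 23.3 ± 1.69 in SNI, and the Notch ligand Dll4 at 1.89 ± 0.145 and 3.54 ± 0.292. Lower values were also seen in Nrp1, a coreceptor of semaphorins and VEGF, at 33.5 ± 1.74 and 40.8 ± 2.81, in Casq2 at 2.21 ± 0.494 and 4.16 ± 0.751 and in Pde8a at 67.8 ± 2.42 and 79.5 ± 3.03. Rida stood higher at 91.7 ± 7.03 and 75.0 ± 0.516, and the purine receptor P2ry1 at 41.3 ± 1.96 and 32.4 ± 2.89.

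**Figure D5:**
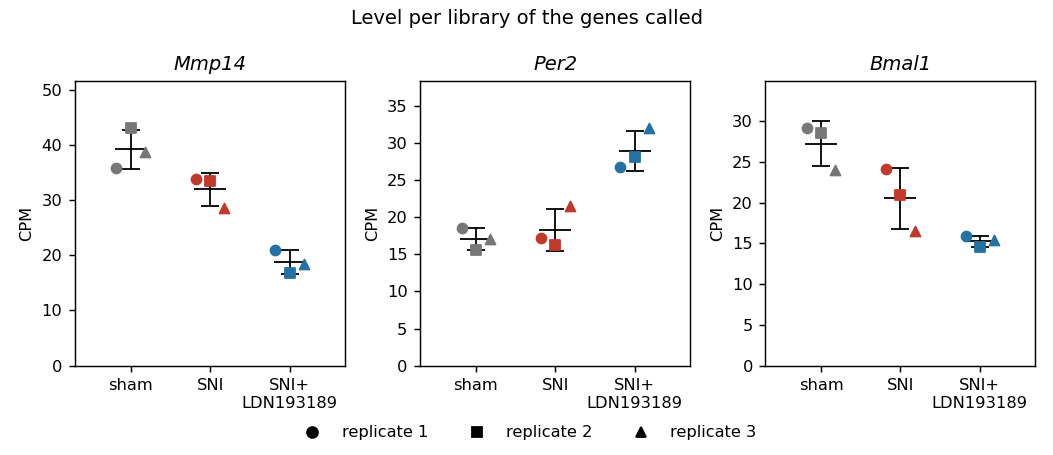
CPM of the genes called by edgeR on a linear axis, with a point per library and the mean ± SD of each group. Mmp14 had a mean of 18.8 CPM in SNI+LDN193189 and stood at 35.9 to 43.0 in sham, Per2 at 26.8 to 31.9 and 15.6 to 18.6, and Bmal1 at 14.6 to 15.9 and 24.1 to 29.1.

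Axotomy genes fell in SNI+LDN193189 against SNI, 16 of 20 being lower. They had risen in SNI against sham, and the shared SNI libraries alone can bring about such an opposite direction. In SNI+LDN193189 against sham camera did not call the list (median 0.04), while DESeq2 called Sprr1a. Vgf, a neuropeptide precursor gene, stood at 109 ± 4.05 CPM in SNI+LDN193189 and 125 ± 12.9 in SNI and the transcription factor Jun at 40.0 ± 5.79 and 46.6 ± 3.37. The log2 fold change of Vgf went from -0.190 to -0.103 without SNI replicate 1 and that of Jun from -0.221 to -0.119 without SNI+LDN193189 replicate 3. Posterior Hox genes, which mark the lumbosacral cord, fell with them, 7 of 8 being lower. SNI+LDN193189 replicate 3 held 0.688 CPM of Sprr1a, 1.15 of Atf3 and 6.85 of Hoxd10, the last chosen after its values were seen. Replicates 1 and 2 held 6.38 and 17.4 of Sprr1a, 5.63 and 9.80 of Atf3, and 40.3 and 39.2 of Hoxd10. Camera gave adjusted p-values of 0.00428 for the axotomy list (median -0.13) and 0.00256 for the Hox list (median -0.43), and each had an adjusted p = 0.688 with an estimated correlation. In both lists 0 members passed adjusted over the list alone or, with edgeR or DESeq2, over all genes. Without SNI+LDN193189 replicate 3 the adjusted p was 0.105 for the axotomy list and 0.294 for the Hox list, and without SNI replicate 2 it was 0.104 for the axotomy list. It was 0.152 for the axotomy list and 0.0532 for the Hox list with the clock score as a covariate.

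Vessel and complement genes moved apart in SNI+LDN193189 against SNI. Endothelial markers fell, 9 of 12 being lower, with the VEGF receptor gene Kdr at 16.0 ± 3.36 CPM in SNI+LDN193189 and 25.8 ± 4.27 in SNI and the tight junction gene Cldn5 at 21.9 ± 1.63 and 28.6 ± 6.03. Complement genes rose, all 13 being higher, with C1qb at 34.2 ± 2.42 and 29.9 ± 3.99. With the nerve root level as a covariate the complement list kept 37.1% of its median and lost its call (adjusted p = 0.317), and with the clock score its direction turned (median -0.034, adjusted p = 0.855). The log2 fold change of C1qb went from 0.195 to 0.119 without SNI replicate 1. Hypoxia genes rose, 10 of 12 being higher. Higd1a, a mitochondrial protein gene, stood at 84.4 ± 1.47 and 76.6 ± 2.72 and the demethylase Kdm3a at 47.0 ± 1.96 and 40.7 ± 3.64, with a log2 fold change of 0.207 that was 0.137 without SNI replicate 2. The camera adjusted p was 0.00204 for endothelium (median -0.14), 0.000371 for complement (median 0.30) and 0.027 for hypoxia (median 0.10), and each had an adjusted p = 0.688 with an estimated correlation. Of their members 0 passed with edgeR, adjusted over the list alone or over all genes, and Kdr passed over all genes with DESeq2 (adjusted p 0.0432). Leaving out SNI replicate 1 gave an adjusted p of 0.0881 for endothelium and 0.0973 for complement, and leaving out SNI+LDN193189 replicate 3 gave 0.0855 for endothelium and 0.0783 for hypoxia. For hypoxia it was 0.262 without SNI replicate 2, 0.0976 without SNI replicate 3, 0.126 without SNI+LDN193189 replicate 1, 0.0912 with the nerve root level as a covariate and 0.0835 with the clock score.

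Markers of other tissue were higher in SNI+LDN193189 against SNI. Their direction was opposite in SNI against sham, which the shared SNI libraries alone can bring about, and no value expected without an effect was computed for these lists. Schwann cell and nerve root markers rose, 9 of 10 being higher (median 0.85), and Pmp2 lay between 6.13 and 13.4 CPM in the 3 SNI+LDN193189 libraries. Muscle markers rose, 11 of 12 being higher, and so did fibroblast markers, 10 of 12 (median 0.27), and erythrocyte markers, 6 of 7 (median 0.48). Oxidative phosphorylation genes rose, 25 of 30 being higher (median 0.03), and pain ion channel genes fell, 18 of 23 being lower (median -0.06). Camera gave adjusted p-values of 0.00112 for nerve root and for muscle, 0.012 for erythrocytes, 0.022 for fibroblasts, 0.0243 for oxidative phosphorylation and 0.0412 for channels. They had an adjusted p = 0.815 for nerve root and muscle, 0.688 for erythrocytes and 0.956 for the rest with an estimated correlation. In these lists 0 members passed adjusted over the list alone or, with edgeR or DESeq2, over all genes. Leaving out SNI replicate 1 gave 0.0946 for nerve root and for fibroblasts. SNI replicate 2 left out gave 0.29 for erythrocytes, 0.299 for fibroblasts, 0.38 for oxidative phosphorylation and 0.641 for channels. Leaving out SNI+LDN193189 replicate 1 gave 0.146 for nerve root and fibroblasts, 0.126 for erythrocytes and channels and 0.134 for oxidative phosphorylation. Leaving out SNI+LDN193189 replicate 2 gave 0.106 for erythrocytes and channels, 0.134 for fibroblasts and 0.0764 for oxidative phosphorylation. For channels it was 0.0639 without SNI+LDN193189 replicate 3. With the clock score as a covariate the direction turned for nerve root (0.929), fibroblasts (0.0597) and channels (0.447), and for erythrocytes the adjusted p was 0.161. The nerve root level as a covariate gave 0.734 for nerve root, 0.361 for fibroblasts, whose direction turned, 0.117 for erythrocytes and 0.364 for channels.

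The lists of the study's title were not called in SNI+LDN193189 against SNI. BMP-SMAD target genes had a median of 0.08 (camera adjusted p = 0.774), and BMP and activin receptors a median of 0.01 and a mean of -0.00 with the test pointing up (adjusted p = 0.976). Glycolysis genes had a median of 0.00 and a mean of -0.01 with the test pointing down (adjusted p = 0.918). Histone lactylation enzymes had a median of 0.00, a mean of -0.01 and a test pointing down (adjusted p = 0.922), and pyroptosis genes a median of 0.06 (adjusted p = 0.23). Reactive microglia genes had a median of 0.01, a mean of -0.06 and a test pointing up (adjusted p = 0.92). Cytokines and chemokines had a median of -0.41 (adjusted p = 0.0962), which was 0.0318 without SNI replicate 1 and 0.00608 without SNI+LDN193189 replicate 2. With the clock score as a covariate it was 0.00948, with a median of -0.515.

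SNI+LDN193189 against sham set the treated injured cord beside the uninjured. Mmp14 fell to 18.8 ± 2.13 CPM from 39.2 ± 3.58, a log2 fold change of -1.06 (SE 0.0987, edgeR adjusted p = 0.000274). Per2 rose to 28.9 ± 2.68 from 17.1 ± 1.46, a log2 fold change of 0.76 (SE 0.112), while Bmal1 fell to 15.3 ± 0.673 from 27.2 ± 2.75, a log2 fold change of -0.83 (SE 0.121), each with an edgeR adjusted p = 0.0374. Clock genes as a list rose, 10 of 13 being higher. Tef, a clock output transcription factor, stood at 258 ± 15.2 and 196 ± 5.68 and Npas2 at 8.15 ± 0.534 and 13.8 ± 2.13. Glucocorticoid genes rose, 13 of 15 being higher, with Tsc22d3 at 202 ± 20.7 and 162 ± 14.1. Camera gave both lists an adjusted p = 3.99e-08, with medians of 0.35 for the clock and 0.32 for glucocorticoid genes, and an adjusted p = 0.278 and 0.542 with an estimated correlation. Adjusted over the list alone 11 clock genes changed, 8 up and 3 down, and 2 glucocorticoid genes rose, Tsc22d3 and Per1, while over all genes 2 clock genes and 0 glucocorticoid genes passed with edgeR. DESeq2 called 8 clock genes and 2 glucocorticoid genes, Per1 and Tsc22d3, at adjusted p-values of 0.00267 and 0.0365. Per2 lies on chromosome 1 at 91415982 to 91459324 and Bmal1, annotated as Arntl, on chromosome 7 at 113207465 to 113314126.

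With edgeR 3 genes passed in SNI+LDN193189 against sham, and 1561 had an unadjusted p under 0.05 (742 higher and 819 lower, 912.25 being expected by chance). DESeq2 called 64, 28 higher and 36 lower, limma-voom called 1 and edgeR without a filter called 30. Mmp14, Per2 and Bmal1 did not overlap between the groups, which chance gives in 10% of genes with 3 libraries against 3. Mmp14 kept its call whichever library was left out, with adjusted p-values of 0.000128 to 0.00714. Per2 lost its call without sham replicate 2 (0.0772), sham replicate 3 (0.0962), SNI replicate 1 (0.0779), SNI replicate 2 (0.0621) and SNI+LDN193189 replicates 1 (0.101), 2 (0.201) and 3 (0.319). Bmal1 lost it without sham replicate 1 (0.0603), sham replicate 2 (0.0774), SNI replicate 2 (0.124) and SNI+LDN193189 replicates 1 (0.108), 2 (0.281) and 3 (0.319). With the clock score as a covariate, a fit added after seeing the data, all 3 genes lost their call. The log2 fold change was then -0.764 for Mmp14 (adjusted p 0.131), 0.432 for Per2 (0.426) and -0.213 for Bmal1 (0.59987). That score contains Bmal1 and can hardly be told apart from these groups. The count was 17 without SNI replicate 3 and 7 without sham replicate 1 or sham replicate 2. It was 2 without sham replicate 3, without SNI replicate 1 and without SNI+LDN193189 replicate 2, and 1 without SNI replicate 2, without SNI+LDN193189 replicate 1 and without SNI+LDN193189 replicate 3. The other genes with the smallest p did not pass with edgeR in the main fit, with adjusted p-values of 0.0925 to 0.162. Among the genes that DESeq2 called were Kank1, Vstm4, Aqp1, Sat1 and Tef. Those called by edgeR without a filter included Kank1, Aqp1, Sat1, Tef, Dapk1 and Tmem100. Kank1, a regulator of the actin skeleton, stood at 31.6 ± 3.63 CPM in SNI+LDN193189 and 47.2 ± 3.27 in sham, Vstm4 at 14.5 ± 2.59 and 28.4 ± 3.91, and Tmem100, an endothelial gene, at 17.1 ± 1.14 and 24.9 ± 0.270. Lower values were also seen in the kinase Dapk1 at 37.5 ± 2.12 and 50.7 ± 5.86, in Aqp1 at 0.867 ± 0.354 and 3.82 ± 1.35 and in Sat1 at 63.5 ± 3.83 and 81.9 ± 6.18. Without SNI replicate 3 Kank1, Aqp1, Vstm4, Tmem100 and Tef passed, at 0.0181, 0.033, 0.0276, 0.0276 and 0.0193. Without sham replicate 1 Vstm4 passed at 0.0329.

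Matrix, vessel and outside-tissue markers were lower and cord and mitochondrial genes higher in SNI+LDN193189 against sham. Extracellular matrix genes fell, 15 of 17 being lower (median -0.49), with the basement membrane collagen Col4a1 at 19.7 ± 5.53 CPM in SNI+LDN193189 and 43.0 ± 19.4 in sham, a log2 fold change of -1.13 that was -0.695 without sham replicate 3. Endothelial markers fell, 10 of 12 being lower (median -0.23), with Cldn5 at 21.9 ± 1.63 and 34.7 ± 4.70 and Kdr at 16.0 ± 3.36 and 26.8 ± 4.49. All 10 nerve root markers (median -1.30), all 9 ganglion neuron markers (median -1.64), all 12 muscle markers and 10 of 12 fibroblast markers (median -0.81) were lower. Microglial markers rose, 12 of 14 being higher (median 0.20), with Csf1r at 77.6 ± 5.17 and 66.0 ± 2.93, and so did myelin genes, 12 of 15 (median 0.11). Mog, a myelin surface protein, stood at 83.1 ± 4.81 and 70.1 ± 7.36. Oxidative phosphorylation genes, 27 of 30 (median 0.09), and tricarboxylic acid cycle genes, 19 of 20 (median 0.08), were higher. Camera gave adjusted p-values of 5.14e-10 for matrix, 1.62e-07 for oxidative phosphorylation, and 9.81e-06 for the tricarboxylic acid cycle and for microglia. It gave 5.85e-05 for myelin, 7.98e-05 for endothelium, 0.000147 for nerve root, 0.000672 for ganglion neurons, 0.00325 for muscle and 0.0105 for fibroblasts. Matrix, both mitochondrial lists, microglia, myelin, endothelium and ganglion neurons had an adjusted p = 0.542 with an estimated correlation, nerve root 0.552, and muscle and fibroblasts 0.659. Adjusted over the list alone 2 matrix, 2 endothelial, 2 microglial, 4 myelin and 1 oxidative phosphorylation gene passed, and over all genes Mmp14 did with edgeR. With DESeq2 Cldn5 (adjusted p 0.00216), Kdr (0.00282) and 1 microglial gene passed as well. Without sham replicate 3 the adjusted p was 0.105 for nerve root and 0.768 for fibroblasts, and without sham replicate 2 it was 0.148 for ganglion neurons. For muscle it was 0.593 without sham replicate 1, with the direction turned, and 0.0532 without SNI+LDN193189 replicate 1. For fibroblasts it was 0.107 without SNI+LDN193189 replicate 3. With the clock score as a covariate the direction turned for ganglion neurons (adjusted p 0.975) and muscle (0.852). The nerve root level as a covariate gave an adjusted p of 0.66 for nerve root and for fibroblasts. With it the matrix list kept 38.1% of its median (-0.187) and stayed called (adjusted p = 0.000114).

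Camera called 8 more lists in SNI+LDN193189 against sham. Heat shock and unfolded protein genes fell, 13 of 17 being lower (median -0.13, adjusted p = 7.98e-05, adjusted p = 0.552 with an estimated correlation), but with the clock score as a covariate they were called higher (median 0.214, adjusted p = 0.00191). Dorsal horn peptide genes fell, 16 of 21 being lower (median -0.12, adjusted p = 0.0442, adjusted p = 0.659 with an estimated correlation), with 2 members past the threshold adjusted over the list alone, 0 with edgeR over all genes and Tac1 with DESeq2 (0.0304). Tac1, the precursor of substance P, stood at 23.7 ± 1.54 CPM in SNI+LDN193189 and 32.3 ± 2.85 in sham, and Sst, which encodes somatostatin, at 59.1 ± 1.12 and 69.6 ± 1.88. Neuronal markers rose, 9 of 14 being higher (median 0.04, adjusted p = 0.0122, adjusted p = 0.659 with an estimated correlation), with Uchl1 at 429 ± 9.51 and 370 ± 36.4 and 2 members past the threshold adjusted over the list alone. Glycolysis genes rose, 16 of 26 being higher (median 0.04, adjusted p = 0.0343, adjusted p = 0.547 with an estimated correlation). Posterior Hox genes fell (median -0.83, adjusted p = 0.0244, adjusted p = 0.598 with an estimated correlation), as did ependymal markers (median -0.34, adjusted p = 0.0244, adjusted p = 0.552 with an estimated correlation). The same held for pericyte markers (median -0.21, adjusted p = 0.0471, adjusted p = 0.659 with an estimated correlation) and neutrophil markers (median -2.81, adjusted p = 0.0263, adjusted p = 0.659 with an estimated correlation). Neutrophil S100a8, chosen after its values were seen, stood at 86.3 CPM in sham replicate 3, and without that library the direction turned (adjusted p 0.0904). Without sham replicate 3 the adjusted p was also 0.841 for neurons, 0.251 for glycolysis, 0.334 for ependyma and 0.852 for pericytes. Without sham replicates 1 and 2 in turn it was 0.163 and 0.79 for dorsal horn peptides and 0.163 and 0.0725 for Hox genes. Leaving out SNI replicate 1 gave 0.0531 for dorsal horn peptides and 0.0554 for pericytes, SNI replicate 2 gave 0.0569 and SNI replicate 3 gave 0.0611 for pericytes. Leaving out SNI+LDN193189 replicate 1 gave 0.164 for dorsal horn peptides, 0.112 for glycolysis, 0.0532 for neutrophils and 0.237 for pericytes. Its replicate 2 left out gave 0.0540 for ependyma, 0.0506 for glycolysis, 0.0933 for neurons and 0.0788 for neutrophils, and its replicate 3 left out gave 0.103 for ependyma, 0.204 for Hox genes and 0.0590 for neutrophils and pericytes. With the nerve root level as a covariate the adjusted p was 0.347 for neurons (median 0.00485), 0.228 for glycolysis, 0.167 for Hox genes, 0.421 for ependyma, 0.804 for neutrophils and 0.288 for pericytes. With the clock score it was 0.0593 for dorsal horn peptides, whose direction turned, and 0.313 for Hox genes.

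The lists of RNA for the study's own subjects were not called in SNI+LDN193189 against sham apart from glycolysis. BMP-SMAD target genes had a median of 0.14 (camera adjusted p = 0.171) and pyroptosis genes a median of 0.08 (adjusted p = 0.165). Each of the next lists had an adjusted p of 0.868. BMP and activin receptors had a median of 0.02, a mean of -0.04 and a test pointing down. Histone lactylation enzymes had a median of -0.02 and a mean of -0.00 with a test pointing up, and reactive microglia genes a median of -0.00 and a mean of -0.14 with a test pointing up. Cytokines and chemokines had a median of -0.09 (adjusted p = 0.0793), which was 0.00511 without SNI+LDN193189 replicate 2 and 0.0311 with the clock score as a covariate (median -0.794).

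Across the 3 groups the genes fixed for the study's subject did not pass with edgeR, at adjusted p-values of 0.744 to 0.992, while Slc2a1 passed with DESeq2. Acvr1 stood at 27.7 ± 2.34 CPM in sham, 29.6 ± 5.78 in SNI and 29.6 ± 2.60 in SNI+LDN193189 (edgeR adjusted p of the 3 groups 0.963). The BMP target genes Id1 and Id3 stood at 9.20 ± 1.37, 9.85 ± 1.05 and 10.4 ± 0.437, and at 23.5 ± 3.32, 21.4 ± 0.893 and 23.5 ± 0.660. Bmpr1a stood at 93.2 ± 4.47, 97.2 ± 1.52 and 98.2 ± 1.65 and the inhibitory Smad6 at 1.93 ± 0.197, 2.32 ± 0.557 and 2.14 ± 0.726. The glucose transporter gene Slc2a1 stood at 117 ± 12.4, 116 ± 6.54 and 147 ± 19.0 (edgeR adjusted p 0.744, unadjusted 0.00766, DESeq2 adjusted p 0.0427). Glycolytic Hk2 stood at 5.40 ± 1.60, 5.16 ± 0.620 and 5.38 ± 0.757, Pfkfb3 at 112 ± 8.19, 120 ± 8.72 and 112 ± 2.39 and Pkm at 1296 ± 69.4, 1368 ± 14.9 and 1390 ± 44.9. The lactate dehydrogenase genes Ldha and Ldhb stood at 83.8 ± 6.28, 76.2 ± 5.92 and 73.5 ± 9.34, and at 503 ± 16.8, 525 ± 18.7 and 544 ± 16.0. Nlrp3, the inflammasome sensor, stood at 1.32 ± 0.234, 1.24 ± 0.298 and 1.32 ± 0.300, the pore protein gene Gsdmd at 2.99 ± 1.01, 3.26 ± 0.754 and 2.96 ± 0.186 and Il18 at 31.5 ± 1.97, 33.3 ± 3.24 and 36.4 ± 2.49. Aif1 of microglia stood at 3.89 ± 0.0785, 5.01 ± 1.35 and 4.71 ± 0.137, Gfap of astrocytes at 1043 ± 98.2, 1156 ± 115 and 1290 ± 254, and the histone acyltransferase gene Ep300 at 69.9 ± 2.42, 68.9 ± 4.36 and 69.2 ± 1.05. Over the 3 groups together 1 gene passed with edgeR, Mmp14 at an adjusted p of 0.0011, while 1083 had an unadjusted p under 0.05 and DESeq2 called 69. The edgeR count was 19 without sham replicate 1, 3 without sham replicate 2 and without SNI replicate 3, and 2 without SNI+LDN193189 replicate 2.

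Genes moved back by the compound were sought in the opposite signs of SNI against sham and SNI+LDN193189 against SNI. With 0 genes called by edgeR in SNI against sham, where 972 had an unadjusted p under 0.05 and DESeq2 called 25, a share of called genes moving back could not be formed. Over all tested genes, which are not independent replicates, the log2 fold changes of both comparisons correlated with r = -0.435. The shared SNI libraries alone gave -0.355 to -0.254 in 100 simulations with SNI means in both injured groups, and -0.526 to -0.470 in 100 simulations with no group effect. Simulated values are given here as limits that leave out the most extreme simulations at each end. The observed covariance of -0.0531 lay inside the limits of -0.0579 to -0.0396 with SNI means in both injured groups. It lay below the limits of -0.0514 to -0.0437 with no effect (mean -0.0472, SD 0.00229), which single simulations can also pass. The simulations with SNI means did not resemble the data in their count of called genes, 212 to 310 where 0 were observed. Genes with an unadjusted p under 0.05 in both comparisons and opposite signs numbered 77, fewer than the 158 to 210 simulated with no effect and the 219 to 277 with SNI means. The simulated tables were fitted without the robust fitting of the main test. Counts that rest on p, these pairs and the called genes, therefore compare unlike fits, and no conclusion is drawn from them. Whether genes moved back beyond what the shared libraries bring about was not settled by these values.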

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

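The fits with the nerve root level or the clock score as a covariate or with counts halved, and the fit without sham replicate 1 and SNI+LDN193189 replicate 3 together, were chosen only after the results had been seen. Where no reason is given, the cause was not tested. Genes called in SNI against sham numbered 0 with edgeR, 25 with DESeq2, 14 with the root covariate, 30 without both doubted libraries, 0 to 38 over the libraries left out and 972 with an unadjusted p under 0.05. The muscle genes Myh4, Myom2, Tnnc2 and Actn2 were among those called with the root covariate here, in SNI+LDN193189 against sham and over the 3 groups. In SNI against sham the muscle list median went from -6.85 to -10.3 with that covariate. Muscle Acta1 stood at 222 CPM in sham replicate 1 and at most 4.16 in any other library. In SNI+LDN193189 against SNI the 1 gene became 2 without a filter, 7 with DESeq2, 3 with only the libraries compared, 0 on log2(FPKM + 1) and 0 on log2(FPKM + 0.1) with a filter. It became 2 with the root covariate, 0 with the clock covariate, 0 without both doubted libraries, 0 with a log2 fold change of at least 1, 0 to 2 over the libraries left out and 708 unadjusted. In SNI+LDN193189 against sham the 3 genes became 30 without a filter, 64 with DESeq2, 1 with limma-voom, 1 on log2(FPKM + 1) and 1 on log2(FPKM + 0.1) with a filter. They became 15 with the root covariate, 0 with the clock covariate, 4 without both doubted libraries, of which only Mmp14 was among the 3 (Per2 at 0.147, Bmal1 at 0.271), 1 with a log2 fold change of at least 1, 1 to 17 over the libraries left out and 1561 unadjusted. The clock score contains Bmal1. It was -0.93 to -0.23 in sham and 0.58 to 0.86 in SNI+LDN193189, so that covariate can hardly be told apart from these groups. Over the 3 groups the 1 gene became 25 without a filter, 69 with DESeq2, 17 with the root covariate, 0 with the clock covariate, 10 without both doubted libraries, 1 to 19 over the libraries left out and 1083 unadjusted. With the replicate numbers as a block, though pairing of the libraries was not shown, the count was 0 in SNI+LDN193189 against SNI and 5 over the 3 groups. The correlation for genes moved back was then -0.50.

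Gene lists called with an estimated correlation or by fry numbered 0 in each comparison. The 19 lists of SNI against sham became 11 with the root covariate and ran from 19 to 24 over the libraries left out, the 13 of SNI+LDN193189 against SNI ran from 8 to 21 and the 20 of SNI+LDN193189 against sham from 18 to 21. The root covariate ended the call of 14, 6 and 8 lists in SNI against sham, SNI+LDN193189 against SNI and SNI+LDN193189 against sham and newly called 6, 5 and 6, and the clock covariate ended 3, 9 and 5 and newly called 9, 11 and 9. With counts halved the lists numbered 19, 12 and 20 and the genes 0, 1 and 3. The correlation for genes moved back ran from -0.563 to -0.358. With the root covariate, which is built from the nerve root list, the camera test pointed the other way for some lists. In 4 cases the median only shrank towards 0, in SNI against sham for nerve root (adjusted p 0.905) and ependyma (0.773) and in SNI+LDN193189 against sham for nerve root (0.66) and fibroblasts (0.66). The median changed sign too in SNI against sham for fibroblasts (0.264), macrophages (0.894) and reactive astrocytes (0.247), and in SNI+LDN193189 against SNI for fibroblasts (0.361). With the clock covariate test and median turned in SNI against sham for heat shock (0.0732), interferon (0.00028), Ifi44 (log2 fold change -0.21) and Rsad2 (-0.21), in SNI+LDN193189 against SNI for nerve root (0.929), complement (0.855), fibroblasts (0.0597) and pain channels (0.447), and in SNI+LDN193189 against sham for dorsal horn peptides (0.0593), heat shock (0.00191), ganglion neurons (0.975) and muscle (0.852). The direction turned for interferon in SNI against sham without SNI replicate 3 (0.0345, in a range of 3.66e-08 to 0.0949 over the libraries left out). In SNI+LDN193189 against sham it turned for neutrophils without sham replicate 3 (0.0904, range 0.000314 to 0.0904) and for muscle without sham replicate 1 (0.593, range 3.52e-06 to 0.593). Among the alternatives not added later 1677 fold changes of named genes kept their direction and side of the threshold, 55 newly passed and 30 no longer did, and 0 turned. Most of the 1677 were of genes not called in either fit, since the main fit called only Mmp14, Per2 and Bmal1. The 30 lost calls were those of Mmp14 against SNI and of Per2 and Bmal1 against sham, so these calls were not stable. For gene lists 800 kept both, 187 no longer passed, 4 newly passed and 3 turned. The fit with only the libraries compared and the fold change threshold could not be given for the 3 groups together. Where a library is left out its group keeps 2, and the spread is pooled over the 3 groups.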

Other observations

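The tests of a swap, of a single wrong label, of the level along the cord and of the hour behind the clock genes, and the counts of splits for genes, were chosen only after the results had been seen, as were the fits with a covariate.

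Lists for transmission within the cord were not called in the main fit. GABA and glycine genes had median log2 fold changes of 0.04 in SNI against sham, -0.02 in SNI+LDN193189 against SNI and 0.01 in SNI+LDN193189 against sham, with camera adjusted p-values of 0.116, 0.206 and 0.868. Glutamate genes had medians of 0.01, -0.04 and -0.03, with adjusted p-values of 0.885, 0.25 and 0.195, the mean being negative at -0.04 in SNI against sham and positive at 0.04 in SNI+LDN193189 against SNI. Immediate early genes had medians of -0.13, -0.01 and -0.06 with adjusted p-values of 0.43, 0.633 and 0.177, and motor neuron markers medians of -0.04, 0.06 and 0.04 with adjusted p-values of 0.879, 0.165 and 0.235, their mean being -0.02 in SNI+LDN193189 against sham. With the nerve root level as a covariate glutamate genes were called lower in SNI against sham (adjusted p 0.000312) and in SNI+LDN193189 against sham (0.00113). With the clock score they were called higher there (0.0322 and 0.0119), so their direction hung on the fit. GABA and glycine genes were called higher with the clock score, with adjusted p-values of 4.19e-05, 0.0468 and 0.000125 in the order above, and motor neuron markers in SNI+LDN193189 against SNI (0.0472). The Y-linked gene Ddx3y stood at 113 to 129 CPM in all 9 libraries, which the labels give as male.

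SNI+LDN193189 replicate 3 held 0.688 CPM of Sprr1a and 6.85 CPM of Hoxd10, far below the other libraries of its group. A swap with a sham library is argued against, since the highest Sprr1a level among sham libraries was 0.235 CPM and the lowest among the other injured libraries was 6.38. Cord taken at another level along its length is a candidate explanation, since the mean centred log2 level of the lumbosacral Hox list was -1.42 in that library and -0.20 to 0.55 in the other 8. A single wrong label on a sham library is argued against by 1 gene only. Mmp14, the 1 gene that edgeR called against sham without that library, stood at 18.5 CPM in it and at 35.9 or more in sham. A wrong label on an SNI library was not settled. Sprr1a stood at 6.62 CPM or more in SNI, but an SNI library from another level of the cord could also hold less. On the 100 genes with the smallest p without it, that library lay 0.80 of the way from sham to SNI+LDN193189 (median), but sham libraries held out in the same way lay at up to 0.69, so that measure decided little. Whether the compound lowers the axotomy list in all treated libraries stays open: without replicate 3 the camera adjusted p was 0.105, in a range of 0.000291 to 0.845 over the alternatives, while 15 of 20 members stayed lower with a median of -0.11. That direction can also come from the SNI libraries shared with SNI against sham, where the list rose. The test had been set to count a lost call against the compound, which was too strict, since fewer libraries also end a call.

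Matrix, fibroblast and macrophage genes were lower in SNI than in sham, where Pmp2, Prx and Acta1 were highest in single sham libraries, and no sorting step is named in the labels. With the nerve root level as a covariate 6.77% of the median log2 fold change of the matrix list was kept, -22.1% of that of the fibroblast list and -1.55% of that of the macrophage list, while the axotomy list kept 85.8%. This is consistent with nerve root and membranes carried in the sham libraries, with Prx, a peripheral nerve gene chosen after its values were seen, at 53.1 to 486 CPM and Col1a1 at 27.2 to 199 CPM there. Of the members 1 of 17, 0 of 12 and 2 of 10 kept over 50% of their change. An effect of the injury on nerve root and membranes themselves stays open as untested, because the root level also differs between the groups.

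Clock genes, glucocorticoid genes and Mmp14 moved together with the compound, and the hour of collection is not in the labels. Libraries collected at different hours are a candidate explanation for the clock genes. The clock score ranged over 1.06 within SNI, more than the 0.70 between the means of SNI+LDN193189 and SNI, though these are unlike measures. SNI replicate 3 at 0.61 lay inside the treated range of 0.58 to 0.86, as did its Dbp, Tef, Per3 and Nr1d1 levels. Outside the treated range there lay Per2 at 21.5 CPM (26.8 to 31.9), Per1 at 37.5 (42.8 to 52.1) and Bmal1 at 16.6 (14.6 to 15.9). The glucocorticoid list kept 93.0% of its median with the clock score as a covariate, 14 of 15 members keeping over 50%. A linear effect of that score as the whole cause is thus argued against for this list. The score only stands in for the hour and its genes were chosen after seeing the data, so the hour itself was not excluded. For Mmp14 the hour cannot be told apart from the compound. Its log2 fold change went from -0.77 (SE 0.0988) to -0.61 (SE 0.114) with the clock score as a covariate, and its edgeR adjusted p to 0.161. Over the alternatives the adjusted p ran from 3.16e-08 to 0.28. The call ended with the clock score as the effect shrank and its error grew. An action of the compound, or of its injection and handling, on steroid signalling stays open as untested.

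Splits of the 6 libraries of a pair of groups number 10 with the real split included, too few for a share under 0.05. In SNI against sham 10 of 10 splits gave as many genes as the real 0 with edgeR (highest other 0, 972 genes with an unadjusted p under 0.05, 25 called by DESeq2). Any split gives at least 0, so that share says nothing about chance. In SNI+LDN193189 against SNI 2 of 10 gave as many as the real 1 (highest other 6), and in SNI+LDN193189 against sham 1 of 10 gave as many as the real 3 (highest other 0). For gene lists, 7 of 10 splits gave as many as the real 19 (highest other 28), 5 of 10 as many as the real 13 (highest other 19) and 5 of 10 as many as the real 20 (highest other 24), in the same order. Of 100 splits of all 9 libraries 13 gave as many genes as the real 1, the real split being counted in both numbers, so chance is not excluded for that count. The highest other gave 36, with sham replicate 1 and SNI replicates 1 and 2 in a group, sham replicates 2 and 3 and SNI+LDN193189 replicate 1 in another, and the rest in the last. The group with sham replicates 2 and 3 held the 3 highest nerve root levels, 0.98, 2.14 and 0.61. The clock score was -0.85, -0.45 and -0.20 in the group with sham replicate 1. In the last group the score was 0.61 to 0.86. In the group with sham replicates 2 and 3 it was -0.93, -0.23 and 0.58, which overlaps the group with sham replicate 1. That split thus followed the nerve root level and only in part the clock score. Whether they gave rise to its count was not tested.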
